A study of Mus musculus with 37 samples.

How the data were processed

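Laser-captured tissue of the hippocampal dentate gyrus (DG) or the nucleus accumbens (NAcc) was taken from 12 µm coronal brain sections of adult male C57BL/6J mice left undisturbed in the morning, per the labels' protocols. RNA isolated with a PicoPure kit went through 2 rounds of RiboAmp amplification, was labelled with biotin and was hybridized to arrays. The mice overexpressed the glucocorticoid receptor in the forebrain in early life (6 DG and 6 NAcc arrays) or for the whole lifetime (6 and 7), or were controls (6 and 6). The 37 arrays came from 19 animals, 18 of them with both regions; the same number in the titles of both regions was taken as the same animal, because the series design states that the areas came from each animal. The labels give no hybridization batch, no litter and no age in days.

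The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which give no version. Each value stands for 1 RefSeq transcript accession, so probes had been grouped by transcript with a definition that the labels do not name, and control probes were not used here. The values ran from 3.23 to 15.2. Array medians were 6.79 to 6.93 in DG and 6.13 to 6.50 in NAcc, so the arrays look normalized within each region and not across regions. Of 24142 deposited accessions, 5307 repeated the values of another and were counted once with it, which left 18835 distinct features. Symbols came from a RefSeq gene table of assembly GRCm38.p6, used for names alone: 20920 accessions matched, and 17260 features carried 1 symbol (16489 genes), 29 several and 1546 none.

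The comparisons, their tests, the gene lists and most alternatives were set before the data were examined. Each region was fitted on its own with limma 3.58.1 in R 4.3.3, with the 3 groups sharing 1 variance per feature. Features under the 40th percentile of the mean (6.34 in DG, 5.77 in NAcc) were left out, so 11301 were tested per region. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 (changed, rose or fell refers to it). DG and NAcc were compared in the 18 animals with the animal as a fixed block, and the difference of the change between regions was tested on the values of DG minus NAcc within each animal. Nr3c1 was also tested with exact permutation of the group labels. An error given as SE is the standard error of limma, and SD is the spread between arrays.

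For gene groups, 38 lists of cell type markers, receptors, channels, signalling and metabolism were written in advance: glucocorticoid-induced genes, stress axis receptors and chaperones, dopamine and cAMP signalling, markers of direct-pathway, indirect-pathway and all medium spiny neurons, granule cells, pyramidal and mossy cells, interneurons, cholinergic neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells and pericytes, blood, choroid plexus and ependyma, meninges, immature neurons, immediate early genes, the circadian clock, receptors for glutamate, GABA, and serotonin and noradrenaline, presynaptic and postsynaptic genes, neuropeptides, potassium and sodium and calcium channels, MAPK and neurotrophin signalling, axon guidance, Wnt signalling, heat shock, myelin lipids, inflammation, oxidative phosphorylation, ribosomal proteins and chromatin. Lists with 5 or more measured genes (32 in DG, 35 in NAcc, 33 in both regions) were tested with limma camera at its preset correlation of 0.01, and again with an estimated correlation. The lists of blood, cholinergic and indirect-pathway markers had fewer in each region and were not tested. Those of direct-pathway neurons, oligodendrocyte precursors, and choroid plexus and ependyma had fewer in DG and were not tested there. A gene with several features was counted in its list by the feature with the highest mean over the 37 arrays. Members were also adjusted over their list alone. The stress axis list holds Nr3c1, the overexpressed gene, and was not tested without it.

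Genes were named by a fixed rule: Nr3c1; the 12 largest rises and 12 largest falls past the threshold in each within-region comparison, or up to 10 with the smallest p; up to 4 members per list with the largest change past the threshold, or up to 2 with the smallest p; the 10 largest differences each way between regions and up to 4 per cell type list; and the 10 smallest adjusted p of each test of the difference between regions. The 8 genes plotted by array follow this rule for a DG comparison, and which of them to plot was chosen after their values were seen. A few genes that the rule names are not reported here, although the counts include them.

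Alternative settings fixed in advance were no filter or a 60th percentile filter, a further quantile normalization, centring of each array on its median, trended and robust variances, array weights, only the 2 groups compared, 1 value per gene, an adjusted p of 0.10, the animal as a random block over both regions (replicate block), no block, control animals only, controls split 3 and 3, and leaving out each array or animal in turn. Alternatives added after the data were seen were the interquartile range of the array, a residual component, or the mean of glial and vascular markers as a covariate, and leaving out NAcc early array 5 alone or with NAcc lifetime array 8. Whether the numbers pair the arrays was checked with the correlation of within-group deviations between the DG and NAcc arrays of the same animal: it ran from −0.197 to 0.473 (mean 0.115, against −0.00590 for other animals), was over 0.1 in 11 of 18 animals, and was highest for the own partner in 3. The pairing therefore rests on the design. The replicate block fits the arrays of both regions together with 1 variance per feature. Calls that it adds or ends can thus come from the pooled variance as well as from the animal.

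The fits were tested on simulated data with 200 changed features of 11301. The simulated noise was independent between features and between arrays, and all features had the same spread in the difference between regions. It held no difference in array range and no correlation between genes, so the false calls below do not give the error rate in the real arrays. In the DG early comparison 74.0% of those changed by 0.5 and 96.0% of those changed by 1 log2 were recovered, in the NAcc early comparison 47.0% and 85.0%, with 8 false calls each, and in the lifetime difference between regions 81.5% of those changed by 1, with 4 false calls. Plots were drawn with matplotlib 3.10.9.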

Results

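Male C57BL/6J mice overexpressed the glucocorticoid receptor in the forebrain either in early life or throughout life, and laser-captured dentate gyrus (DG) and nucleus accumbens (NAcc) of the adults were compared with those of control mice. Nr3c1, the gene of the glucocorticoid receptor, had a mean log2 signal of 8.11 ± 0.13 (SD, n = 6) in control DG, 8.26 ± 0.16 (n = 6) after early and 8.36 ± 0.20 (n = 6) after lifetime overexpression. In NAcc the means were 7.40 ± 0.14 (n = 6), 7.45 ± 0.34 (n = 6) and 7.75 ± 0.24 (n = 7). None of the 6 differences passed the threshold in limma. The DG difference from control was +0.15 (SE 0.10, adjusted p = 0.274, above the control mean in 5 of 6 arrays) in the early group and +0.25 (SE 0.10, adjusted p = 0.0757, 6 of 6) in the lifetime group. In NAcc it was +0.04 (SE 0.14, adjusted p = 0.917, 4 of 6) and +0.35 (SE 0.14, adjusted p = 1.0, 6 of 7). Two-sided exact permutation tests gave p = 0.0346 for DG lifetime and 0.0111 for NAcc lifetime, or 0.104 and 0.0664 after adjustment over the 6 contrasts. The NAcc lifetime difference passed with array weights (+0.42, adjusted p = 0.0214) and without NAcc early array 5 and NAcc lifetime array 8 (+0.42, adjusted p = 0.0295). The DG early difference was −0.02 with the interquartile range of each array as a covariate, and the NAcc early difference was −0.005 after a further quantile normalization and +0.17 without NAcc early array 5. The deposited table holds 1 Nr3c1 feature and no probe sequences, so whether it reads the transgene is not known.

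The arrays themselves differed between the DG groups. The interquartile range of the log2 values was 2.71 ± 0.04 (SD, n = 6) in control DG, 2.85 ± 0.09 (n = 6) in the early group and 2.87 ± 0.10 (n = 6) in the lifetime group. Two-sided exact permutation tests gave p = 0.00649 (early, adjusted over 6 contrasts 0.0195) and p = 0.00216 (lifetime, adjusted 0.0130), and 0.703 between the overexpressing groups. In NAcc, array 5 of the early group stood apart: its median was 6.503, its interquartile range 1.72 and its mean correlation with the other NAcc arrays 0.598, against correlations of 0.961 to 0.966 for the other early arrays. NAcc lifetime array 8 had the highest median of its group (6.27, the others 6.13 to 6.18).

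**Figure D1:**
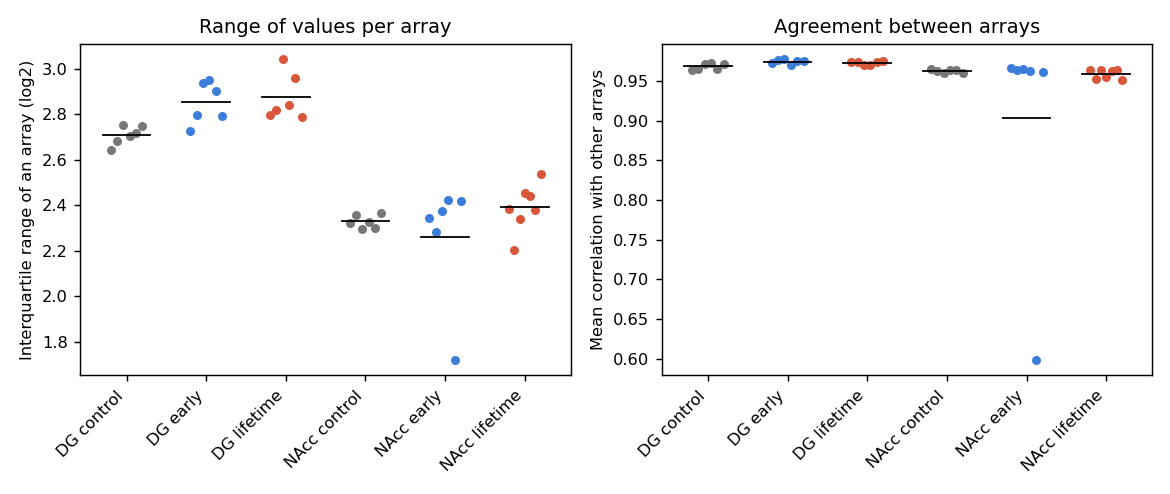
Interquartile range of the log2 values (left panel) and mean Pearson correlation with the other arrays of the same region (right panel) for each of the 37 arrays. Points are arrays and lines group means. All DG groups lay above 2.64 in range, NAcc early array 5 had a range of 1.72 and a correlation of 0.598.

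The regions carried their known neuronal identities. Among 18 animals with both regions, the median of all tested features was 0.71 log2 higher in DG than in NAcc, and the changes in this paragraph are given relative to that shift. Among the largest DG excesses were those of the granule cell markers Lct, +6.59 (SE 0.07), and Dsp, which encodes the junction protein desmoplakin, +6.36 (SE 0.08). The neuronal transcription factors Bhlhe22 (+5.99), Prdm8 (+5.05) and Neurod1 (+4.64) were also higher in DG, each in 18 of 18 animals. Slc35d3 (−5.75, SE 0.16), Strip2 (−5.61, SE 0.16) and Kcna5 (−5.32, SE 0.12) were among the largest NAcc excesses. Medium spiny neuron genes with a NAcc excess included the dopamine receptor gene Drd1 (−4.45, SE 0.15), the enkephalin precursor Penk (−4.50, SE 0.17) and the transcription factor Foxp2 (−4.19, SE 0.21), again in 18 of 18 animals. Counts, medians and means of lists in this paragraph are from before the shift was taken off, where 9354 of all 11301 features passed as higher in DG. All 21 measured granule cell markers were higher in DG (camera adjusted p = 0.000857, or 0.326 with an estimated correlation). Of 15 markers shared by medium spiny neurons, 12 were lower and 2 higher in DG before the shift was taken off (adjusted p = 1.54e-24; 0.000203 with an estimated correlation). A lower list was also found for dopamine and cAMP signalling (11 of 22 lower, 8 higher, adjusted p = 0.00475 with an estimated correlation), direct-pathway markers (4 of 6 lower, 2 higher, 0.0295) and neuropeptides (6 of 17 lower, 8 higher, 0.0394; median +0.21, mean −0.33).

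Markers of other cells were present in both regions. Against all genes, DG was lower for interneuron (adjusted p = 0.000857), astrocyte (0.000857), oligodendrocyte (3.28e-05), microglia (0.00353), endothelial and pericyte (0.0225) and meningeal markers (3.50e-05), and for GABA receptor and transport (0.00192) and myelin lipid and cholesterol genes (8.68e-05). None of these 8 held with an estimated correlation (adjusted p = 0.118 to 0.484). Except for the meninges (median −0.19), their medians were above 0 before the shift was taken off, and the direction refers to the other genes on the array. Relative to the shift, the astrocyte filament gene Gfap was at +1.28 (SE 0.18) and the glutamine synthetase gene Glul at −1.70 (SE 0.08). On the same scale, named interneuron markers went both ways. Cck was at +1.9 and Vip at +1.2, against Gad2 at −2.9 and Slc32a1 at −3.2. The lower interneuron list therefore does not show fewer interneurons in DG. In all, 10113 of 11301 features differed between the regions on the deposited scale (9354 higher and 759 lower in DG), and 3368 by over 1 log2 before the shift was taken off. Of these 10113, 5648 lay above the median shift and 4464 below it, and no test was made against the shift. Kdr, Esam, Fcrls, Enpp2, Slc2a1, Ugt8a, Cnp, Grik3, Ogn and Gpr17 passed as higher in DG on the deposited scale (Kdr +0.70 to Gpr17 +0.21) but lay at or below the shift, and all 10 were lower in DG after quantile normalization of all arrays (Kdr −0.002 to Gpr17 −0.51). The labels give no hybridization batch, so any batch between regions could not be separated from region.

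Early overexpression was accompanied by many moderate changes in DG. Sowaha rose by 1.27 (log2, SE 0.14, adjusted p = 0.000325, above the control mean in 6 of 6 arrays). Nop58, a core protein of nucleolar ribonucleoproteins, rose by 1.07 (SE 0.18, adjusted p = 0.00579, 6 of 6). Ddit4, a stress-induced inhibitor of mTOR signalling and a known glucocorticoid target, rose by 1.02 (SE 0.28, adjusted p = 0.0295, 6 of 6). The largest falls were in Bend5 (−1.22, SE 0.28, adjusted p = 0.0173) and Crhbp, which encodes the binding protein of corticotropin-releasing hormone (−1.16, SE 0.29, adjusted p = 0.0228). The transcription factor gene Fezf2 (−1.06, SE 0.32, adjusted p = 0.0395) and the G protein subunit gene Gng13 (−0.91, SE 0.19, adjusted p = 0.0111) fell as well, and all 4 did so in 6 of 6 arrays. In total 1291 of 11301 features passed (697 higher, 594 lower, 1163 genes), with a median size of 0.37. With each array centred on its median 1102 were higher and 314 lower. The DG arrays of this group also had the wider range of values given above. With that range as a covariate 1 call was left (Sowaha, +0.97, adjusted p = 0.0283), and with the animal as a block 511 features passed. Without early arrays 3, 4 or 5 the count was 347, 213 or 507. Without early array 1 it was 2273, and without control arrays 14, 15 or 17 it was 597, 838 or 757. Of 86 named genes that passed, 16 passed without each array in turn.

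No list of this group passed with the array range as a covariate. Without it, granule cell markers were higher as a list: 20 of 21 were above control (median +0.14), 4 passed and none fell, or 5 adjusted over the list alone (adjusted p = 0.0144; adjusted p = 0.717 with an estimated correlation). The 4 were Sema5a, a guidance semaphorin (+0.68, SE 0.17), the cytokine gene Il16 (+0.58), Dsp (+0.47) and the transcription factor gene Neurod2 (+0.41). Microglial markers were lower as a list (12 of 14 below control, median −0.21, adjusted p = 0.0410; adjusted p = 0.717 with an estimated correlation), with 1 passing member, the signalling adaptor Tyrobp (−0.69, SE 0.14, adjusted p = 0.0114, 6 of 6; 1 adjusted over the list alone). Other glial and vascular markers had medians below 0 without passing as lists: astrocytes (−0.15, 1 rose and 1 fell of 18, adjusted p = 0.302), oligodendrocytes (−0.13, 0 of 18, adjusted p = 0.302) and endothelial cells and pericytes (−0.17, 1 fell of 12, adjusted p = 0.195). Ion channel genes went both ways. Of 26 sodium and calcium channel genes 5 rose and none fell, or 6 and 3 adjusted over the list alone (list median −0.05, mean +0.01, test upward, adjusted p = 0.944). Among them were Cacna1c (+0.68, SE 0.15) and Cacna1h (+0.66, SE 0.18), pore subunits of L-type and T-type channels. Of 25 potassium channel genes 1 rose and 3 fell (adjusted p = 0.302), including Kcnh7 (−0.38, SE 0.09).

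Single genes of the stress axis and of receptors passed in the early group, and none of the lists in this paragraph did. Of 19 stress axis receptor and chaperone genes 4 rose and 2 fell (adjusted p = 0.302). Among them were Hsp90ab1, a chaperone of steroid receptors (+0.88, SE 0.24, adjusted p = 0.0280, 6 of 6), Npy1r (+0.51, SE 0.15) and Crhbp. Of 24 glucocorticoid-induced genes only Ddit4 rose and Sult1a1 fell (−0.34, SE 0.10), against 1 up and 4 down adjusted over the list alone (median −0.04, adjusted p = 0.682). Gria1, an AMPA receptor subunit, rose by 0.71 (SE 0.22, adjusted p = 0.0441, 5 of 6), the 1 of 17 glutamate receptor genes to pass (list median −0.03, mean +0.06, test upward, adjusted p = 0.682). Of 21 postsynaptic density genes 3 rose (adjusted p = 0.302), including Lrrc4 (+0.61) and Dlgap1 (+0.48, SE 0.07, adjusted p = 0.00553, 6 of 6). Of 35 axon guidance genes 4 rose and 3 fell (median +0.01, mean +0.02, test downward, adjusted p = 0.996). The risers included Epha7 (+0.70), Nrp2 (+0.57) and Nrp1 (+0.53). Of 69 oxidative phosphorylation genes 1 rose and 6 fell (adjusted p = 0.311), among them Ndufb8 (−0.44, SE 0.09, adjusted p = 0.0111, 6 of 6). Interneuron markers had 2 falls in 12 (adjusted p = 0.311): Htr3a (−0.32, SE 0.08) and the peptide gene Cck (−0.40, SE 0.11), whose adjusted p was 0.0311, or 0.393 with the animal as a block. Dopamine and cAMP signalling (20), pyramidal and mossy cell markers (11) and immediate early genes (17) had no passing member. Among pyramidal and mossy cell markers the smallest p was that of Grik4 (−0.28, adjusted p = 0.0561), and among immediate early genes that of Dusp1 (−0.81, adjusted p = 0.0666).

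Lifetime overexpression gave the largest changes of the series in DG. Prss23, a serine protease gene, rose by 3.36 (log2, SE 0.16, adjusted p = 7.16e-11), from 5.45 ± 0.38 to 8.82 ± 0.31 (SD, n = 6 each). Blnk, an adaptor of B cell receptor signalling, rose by 2.55 (SE 0.14, adjusted p = 4.43e-10), Tbr1, a transcription factor of newly formed glutamatergic neurons, by 2.21 (SE 0.22, adjusted p = 6.93e-06) and the carbonic anhydrase gene Car4 by 2.13 (SE 0.16, adjusted p = 9.12e-08). Inhba, which encodes the activin A subunit, rose by 1.53 (SE 0.10, adjusted p = 1.73e-08) and the potassium channel gene Kcnk2 by 1.56 (SE 0.17, adjusted p = 1.93e-05). Rgs13, a regulator of G protein signalling, fell by 1.70 (SE 0.30, adjusted p = 0.00175), and the prostaglandin reductase gene Ptgr1 fell by 1.58 (SE 0.16, adjusted p = 6.93e-06). The neuropeptide Y receptor gene Npy2r (−1.37, SE 0.29, adjusted p = 0.00660) and the chemokine gene Cxcl12 (−1.31, SE 0.16, adjusted p = 3.80e-05) fell too. All of these held in 6 of 6 arrays. Of 3 Cxcl12 features 1 passed and 1 had the opposite sign. In total 1733 of 11301 features passed (1004 higher, 729 lower, 1581 genes; median size 0.39). With each array centred on its median 1396 were higher and 471 lower. The arrays of this group had the wider range of values given above. With that range as a covariate 74 features passed, 71 of them among the 1733. They held 22 of the 103 named genes that had passed, including every gene named so far in this paragraph. With the animal as a block 948 features passed. Without lifetime arrays 7, 9 or 11 the count was 1124, 808 or 1011, and without lifetime array 10 it was 2611. In all, 65 of the 103 named genes passed without each array in turn.

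**Figure D2:**
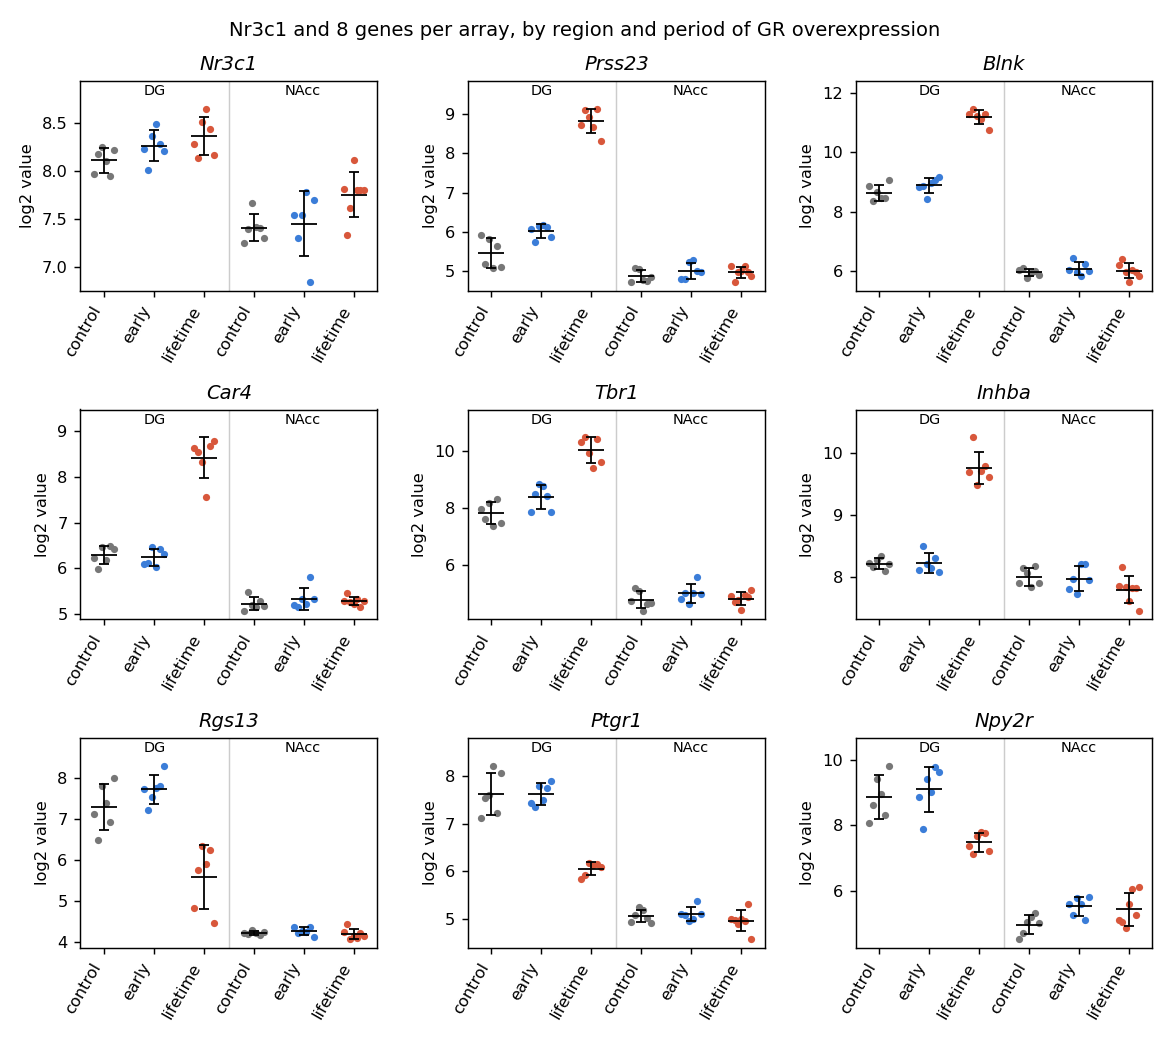
Log2 signal of Nr3c1 and of 8 genes in each of the 37 arrays by region and group; points are arrays, bars group means and error bars SD. The 8 genes, chosen after their values were seen, are the 5 largest rises and 3 largest falls of DG lifetime against DG early; Prss23 averaged 5.45 in control, 6.02 in early and 8.82 in lifetime DG.

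Immature neuron genes were higher as a list after lifetime overexpression, and the other lists in this paragraph did not pass. Of 12 immature neuron and neurogenesis genes 3 rose and 1 fell, or 7 and 1 adjusted over the list alone (median +0.34, adjusted p = 0.0230; adjusted p = 0.820 with an estimated correlation). Tbr1, the neuronal tubulin Tubb3 (+0.77, SE 0.22) and Sox11 (+0.49, SE 0.13) rose. The progenitor filament gene Nes fell (−0.25, SE 0.07, adjusted p = 0.0313, or 0.257 with the animal as a block). Of 21 postsynaptic density genes 5 rose and none fell (median +0.02, adjusted p = 0.319), including Camk2b (+1.24, SE 0.36) and the scaffold gene Homer2 (+0.71, SE 0.11, adjusted p = 0.000480, 6 of 6). Potassium channel genes split, 3 up and 5 down of 25 (adjusted p = 0.537), with Kcnk2 and Kcnk1 (+0.56) against Kcnip4 (−0.94) and Kcnq3 (−0.49). Glutamate receptors had Gria1 up (+0.80) and the kainate receptor genes Grik3 (−0.64) and Grik4 (−0.58) down, 1 and 2 of 17 (median +0.002, mean +0.03, test downward, adjusted p = 0.868). Granule cell markers had 6 up and 2 down of 21 (median +0.02, adjusted p = 0.737). Tdo2, a tryptophan-degrading enzyme (+1.14, SE 0.25), Sema5a (+0.69) and Il16 (+0.67) rose, and Ntng1 fell (−0.71, SE 0.21).

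Glucocorticoid-induced genes had 6 rises and no fall of 24 after lifetime overexpression, or 8 and 1 adjusted over the list alone (median +0.06, adjusted p = 0.378). They included Ddit4 (+1.12, SE 0.28, adjusted p = 0.0146, 5 of 6), Gadd45g (+0.68, SE 0.19) and Sgk1, a glucocorticoid-induced kinase (+0.61, SE 0.15, adjusted p = 0.0102, 6 of 6; 0.182 with the animal as a block). Of 19 stress axis genes 2 rose and 3 fell (adjusted p = 0.537), among them Npy2r and Crhbp (−0.87, SE 0.29, adjusted p = 0.0499, 5 of 6). Among 17 immediate early genes 3 rose (adjusted p = 0.799), the transcription factor gene Jun (+0.78, SE 0.20), the neurotrophin gene Bdnf (+0.51, SE 0.12) and the pentraxin gene Nptx2 (+0.30, SE 0.09). Of the glial marker lists 2 passed. Oligodendrocyte markers were lower (16 of 18 below control, median −0.31, 1 passed, or 1 adjusted over the list alone, adjusted p = 0.0230; adjusted p = 0.867 with an estimated correlation), with Sox10 at −0.34 (adjusted p = 0.0159, or 0.0686 with the animal as a block). Microglial markers were lower as well (13 of 14, median −0.19, 2 passed, or 3 adjusted over the list alone, adjusted p = 0.0230; adjusted p = 0.820 with an estimated correlation), with Tyrobp (−0.56, SE 0.14) and Tmem119 (−0.28, adjusted p = 0.0497, or 0.0628 with the animal as a block). The astrocyte list did not pass (0 of 18, median −0.11, adjusted p = 0.537). These counts use 1 feature per gene, and the other feature passed for Enpp2, an oligodendrocyte marker (−0.76, SE 0.25, adjusted p = 0.0466, 5 of 6; −0.61 and 0.130 for the counted one), and for Slc4a4, an astrocyte marker (+0.34, SE 0.11, adjusted p = 0.0489, 6 of 6; +0.27 and 0.0936). With the array range as a covariate the oligodendrocyte and immature neuron lists still passed (adjusted p = 0.00104 and 0.0136) and the microglial list did not. With this covariate no list held with an estimated correlation. Pyramidal and mossy cell markers went both ways, 2 up and 1 down of 11 (adjusted p = 0.911), with Bok at +0.41 and Grik4 at −0.58. Of 28 ribosomal protein genes 5 rose and none fell (adjusted p = 0.196), and of 69 oxidative phosphorylation genes 8 rose and 2 fell (adjusted p = 0.737).

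The overexpressing groups were compared directly in DG, where their array ranges were alike. Prss23 was higher in the lifetime than in the early group by 2.80 (log2, SE 0.16, adjusted p = 2.19e-09), Blnk by 2.30 (SE 0.14), Car4 by 2.19 (SE 0.16), Tbr1 by 1.65 (SE 0.22) and Inhba by 1.53 (SE 0.10), each in 6 of 6 arrays. Crym, a thyroid hormone binding protein (+1.47, SE 0.21, adjusted p = 0.000493), Plcxd3 (+1.40, SE 0.14), the activin antagonist Fst (+1.17, SE 0.14, adjusted p = 8.46e-05) and the cAMP phosphodiesterase Pde4b (+1.05, SE 0.12) were higher too. Rgs13 (−2.14, SE 0.30, adjusted p = 0.000441) was the lowest, and lower as well were Npy2r (−1.60, SE 0.29), Ptgr1 (−1.58, SE 0.16), Cxcl12 (−1.44, SE 0.16; its other 2 features had the opposite sign), Doc2b, a calcium sensor of vesicle release (−1.17, SE 0.11), Popdc3 (−1.11, SE 0.14) and the transcriptional cofactor Lmo1 (−1.06, SE 0.18), all in 6 of 6 arrays. In total 155 features passed (88 higher, 67 lower, 147 genes; median size 0.55). Of the 41 named genes that passed, all 41 passed with the array range as a covariate, 31 without each array in turn and 36 with the animal as a block. The 5 lost with the block were Kcnk2 (adjusted p = 0.120), Gadd45b (0.0793), Pdzd2 (0.193), Rasd2 (0.145) and Sostdc1 (0.0623).

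Glucocorticoid-induced genes were higher in the lifetime than in the early group as a list, 21 of 24 above (median +0.11, adjusted p = 0.00674; adjusted p = 0.312 with an estimated correlation). The growth-arrest gene Gadd45b passed (+0.50, SE 0.10, adjusted p = 0.0155, 6 of 6), or 3 genes adjusted over the list alone. Oxidative phosphorylation genes were higher in 55 of 69 (median +0.09, adjusted p = 0.00674; adjusted p = 0.652 with an estimated correlation) with no passing member, and 0 adjusted over the list alone. Granule cell markers were lower as a list (median −0.09, adjusted p = 0.00674; adjusted p = 0.733 with an estimated correlation), with 1 up and 3 down of 21, or 2 and 8 adjusted over the list alone. C1ql3, a secreted synaptic protein (−0.53, SE 0.13, adjusted p = 0.0387), Dsp (−0.57, SE 0.14, adjusted p = 0.0472) and Scn3b (−0.45, SE 0.10, adjusted p = 0.0313) fell and Pdzd2 rose (+0.28, SE 0.06, adjusted p = 0.0222). Pyramidal and mossy cell markers had a median of +0.18 in 11 (1 up, Bok, +0.57, adjusted p = 0.00551; list adjusted p = 0.121), oligodendrocyte markers −0.18 in 18 (none passed, adjusted p = 0.0561) and microglial markers −0.02 in 14 (mean +0.002, test downward, adjusted p = 0.820). The cell cycle gene Ccnd2 fell (−0.52, SE 0.12, adjusted p = 0.0233, 6 of 6), beside Tbr1 the other passing gene of 12 immature neuron genes (adjusted p = 0.193). The calls of C1ql3, Dsp, Scn3b, Pdzd2 and Ccnd2 each ended without 1 of the arrays.

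**Figure D3:**
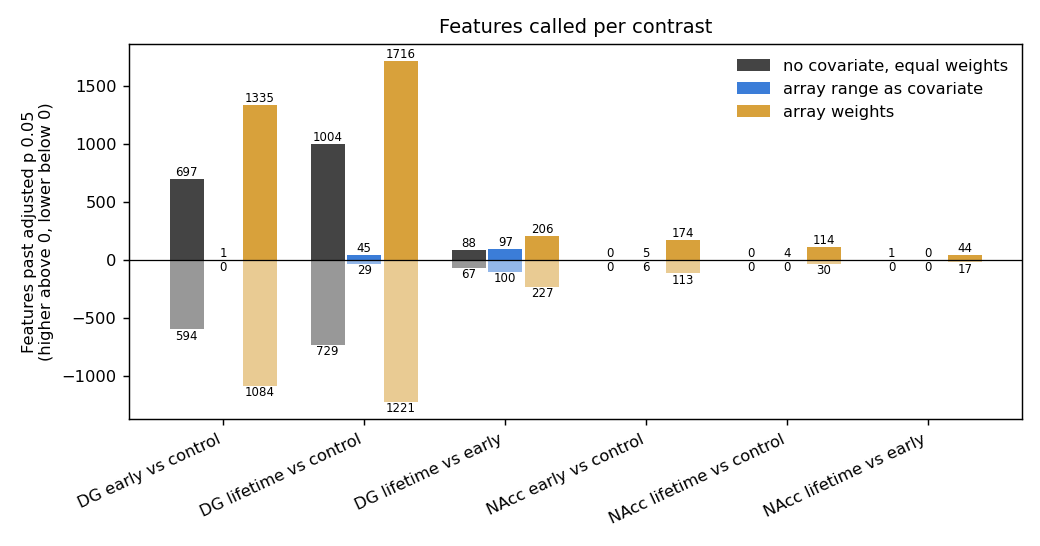
Number of features higher and lower past an adjusted p of 0.05 in each within-region contrast with no covariate and equal array weights, with the interquartile range of each array as a covariate, and with array weights. DG lifetime against early had 155 features without and 197 with the covariate; DG early against control had 1291 and 1.

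The changes of the early and lifetime groups correlated in DG, where both groups also had a wider array range than control. Splitting the controls does not remove that shared difference. Of the features that passed in both, 398 were higher in both (61.9 by chance from the separate counts), 327 lower in both (38.3 by chance) and 1 opposite; the counts share the controls. The correlation of the changes across features, which are not independent replicates, was r = 0.784, against 0.479 ± 0.229 (SD of 100 simulations) for unchanged groups against shared controls, with a covariance of 0.0480 against 0.00846 (highest 0.0226). With the controls split 3 and 3, so that none was shared, r averaged 0.565 (0.423 to 0.657 over 20 splits). In NAcc r was 0.117, and −0.05 with the controls split 3 and 3. Without NAcc early array 5 and lifetime array 8 it was 0.655, against 0.486 ± 0.153 for unchanged groups and 0.347 with the controls split (0.171 to 0.531). The changes in DG and in NAcc correlated at r = −0.218 in the early group (28 of 100 regroupings of the animals gave as much). The lifetime value was r = 0.306 (11 of 100). The early value was 0.190 without animals 5 and 8.

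In NAcc no feature passed after early overexpression (limma; 556 of 11301 had an unadjusted p under 0.05, with 565 expected). The smallest p values belonged to the presynaptic adhesion gene Nrxn2 (+0.58, SE 0.10, adjusted p = 0.156, 6 of 6 arrays), Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP (−0.45, SE 0.09, adjusted p = 0.257, 6 of 6; 0.00926 with the animal as a block), and the sodium channel subunit gene Scn4b (−1.43, SE 0.30, adjusted p = 0.257, 6 of 6; 0.00926 with the block). With the animal as a block 5 features passed, in a fit that shares 1 variance over both regions. With array weights 287 passed, with the array range as a covariate 11, and without NAcc early array 5 and lifetime array 8 together 9. NAcc early array 5, which stood apart, is in this group.

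Medium spiny neuron genes were lower as a list in the early NAcc group: 14 of 15 shared markers were below control (median −0.34, none passed, or 2 adjusted over the list alone, adjusted p = 6.95e-08; adjusted p = 0.177 with an estimated correlation), including Pde10a (−0.34, SE 0.11, adjusted p = 0.784). The same direction held for dopamine and cAMP signalling (19 of 23, median −0.29, or 1 adjusted over the list alone, adjusted p = 0.000175; adjusted p = 0.214 with an estimated correlation). It held too for oxidative phosphorylation (57 of 69, median −0.25, adjusted p = 1.36e-07; 0.734 with an estimated correlation), ribosomal proteins (18 of 24, median −0.17, adjusted p = 0.00686; 0.734) and oligodendrocyte markers (15 of 19, median −0.20, adjusted p = 0.0303; 0.774). Higher as lists were axon guidance genes (26 of 35, median +0.12, adjusted p = 0.00318; adjusted p = 0.214 with an estimated correlation), meningeal markers (7 of 8, median +0.30, or 1 adjusted over the list alone, adjusted p = 0.0157; 0.734), with the proteoglycan gene Dcn at +0.61 (SE 0.19, adjusted p = 0.784). So were immature neuron genes (10 of 11, median +0.14, adjusted p = 0.0422; 0.344). No member of these 8 lists passed over all features. Without array 5 of the early group 4 lists passed: shared medium spiny neuron markers (adjusted p = 1.68e-10), dopamine and cAMP signalling (0.00341), axon guidance and oxidative phosphorylation (0.0329 each). The ribosomal, oligodendrocyte, meningeal and immature neuron lists did not. Without array 5 none of the 4 held with an estimated correlation. Markers of direct-pathway neurons (4 of 6 below control, adjusted p = 0.212), oligodendrocyte precursors (3 of 5 below, median −0.03, mean +0.04, test upward, adjusted p = 0.984) and choroid plexus and ependyma (3 of 6 above, adjusted p = 0.367) did not pass.

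After lifetime overexpression no NAcc feature passed either (limma; 415 of 11301 with an unadjusted p under 0.05). Pcdh19, a protocadherin gene, had the smallest p (+1.08, SE 0.18, adjusted p = 0.112, 7 of 7; 0.000281 with the animal as a block, the 1 feature to pass there), followed by Sox11 (+0.62, SE 0.12, adjusted p = 0.271, 7 of 7). Crh, the gene of corticotropin-releasing hormone, was at +1.82 (SE 0.56, adjusted p = 1.0, 7 of 7). Without NAcc early array 5 and lifetime array 8, 279 features passed (221 higher, 58 lower), among them Pcdh19 (adjusted p = 9.75e-06) and Crh (+2.01, adjusted p = 0.0241); without early array 5 alone 5 passed, and with array weights 144. This set of arrays was chosen after the values were seen.

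Astrocyte markers were higher as a list in the lifetime NAcc group, 17 of 18 above control (median +0.16, adjusted p = 3.63e-05; adjusted p = 0.376 with an estimated correlation), with the glutamate transporter gene Slc1a3 at +0.22 (SE 0.07, adjusted p = 1.0). Shared medium spiny neuron markers were lower in 14 of 15 (median −0.14, adjusted p = 3.63e-05; adjusted p = 0.210 with an estimated correlation), among them Ppp1r1b at −0.27 (SE 0.09) and Pde1b at −0.32 (SE 0.12). Stress axis genes were higher (15 of 17, median +0.17, adjusted p = 0.00144; 0.210 with an estimated correlation, 0.0469 without NAcc early array 5, and 0.0501 without lifetime array 8 as well). So were axon guidance genes (26 of 35, median +0.06, adjusted p = 0.00325; 0.210) and GABA receptor and transport genes (19 of 20, median +0.14, adjusted p = 0.00816; 0.763). Ribosomal protein genes were lower (18 of 24, median −0.08, adjusted p = 0.00144; 0.690). No member of these 6 lists passed, and 0 passed adjusted over the list alone. The stress axis list holds Nr3c1 itself (+0.35, SE 0.14), so its result is not apart from the overexpression. Against the early NAcc group, 1 feature passed, Lrrc58 (+0.64, SE 0.10, adjusted p = 0.0453, 7 of 7; adjusted p = 0.0561 with the array range as a covariate, and 0.184 without early array 1). No feature passed there without any 1 early array or without 1 of the other arrays, except lifetime array 8 or control array 15 (2 each) and control array 17 (1). The actin gene Actb followed (+0.63, SE 0.10, adjusted p = 0.0545, 7 of 7). Its 8 passing lists were higher for astrocytes (17 of 18, adjusted p = 3.61e-05, or 2 adjusted over the list alone), oxidative phosphorylation (0.00178), GABA genes (0.00284), dopamine and cAMP signalling, oligodendrocytes and myelin lipids (0.0310 each), and lower for the meninges (8 of 8, 0.00550) and inflammation (13 of 14, 0.0310). None held with an estimated correlation (adjusted p = 0.826 to 0.856), and the early side of this contrast holds array 5. Without it the astrocyte, oligodendrocyte and meningeal lists passed, with shared medium spiny neuron markers higher and ribosomal protein genes lower (adjusted p = 0.00678 and 0.00364), and the other 5 did not. Without array 5 no list held with an estimated correlation either.

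Whether the change differed between regions was tested within animals. The lifetime change was larger in DG than in NAcc for Blnk (by 2.47, SE 0.17, adjusted p = 1.79e-07), Tbr1 (by 2.22, SE 0.25), Car4 (by 2.07, SE 0.18) and Inhba (by 1.69, SE 0.13), and for the protease gene Capn3 (1.31), Fst (1.21) and Smim3 (1.0). It was lower in DG for Pcdh19 (−1.51, SE 0.21, adjusted p = 0.00119), Spata13, a guanine nucleotide exchange factor (−1.10, SE 0.14), and the potassium channel interacting protein gene Kcnip4 (−1.03, SE 0.15). Prss23, at 4.87 to 5.01 on average in the NAcc groups, did not reach the intensity filter of this test. Tbr1, Car4, Capn3, Fst and Smim3 lay under the NAcc intensity filter, so a fall in NAcc might not show. A rise could show, as for Prss23 in DG, which rose from 5.45, under the DG filter of 6.34. In total 62 features passed (43 higher, 19 lower), and all 10 genes named here passed without each animal in turn. The count was 107 with no animal block and 31 after quantile normalization. Without animals 5 or 10 it was 397 or 187, and without 7, 8, 9, 11, 14, 16 or 17 it was 35, 40, 36, 29, 37, 41 or 36. As lists, ribosomal protein genes were higher in DG (22 of 26, adjusted p = 0.00252; 0.698 with an estimated correlation), as were immature neuron and postsynaptic density genes, and astrocyte and oligodendrocyte markers were lower (adjusted p = 0.0330 each; adjusted p = 0.680 to 0.815 with an estimated correlation). For the early change no feature passed (limma; 2206 with an unadjusted p under 0.05), no list passed. Bend5 had the smallest p (−1.50, SE 0.27, adjusted p = 0.0965). Without animal 5 or animal 10, 30 features passed, and without animals 5 and 8 together 36.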

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

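The comparisons and their counts were planned, and the tests of explanations in this part were chosen only after the result was seen. Among 72 groups of values checked for a single array far from its group, 7 had one, and chance marks about 1 in 20 groups (3.6 here). Most of the 7 were the same array, NAcc early array 5, so the checks were not independent. The 7 and the 3.6 therefore cannot be compared as separate events. The lifetime change differed between DG and NAcc, by a test of the difference itself, for Blnk (2.473), Tbr1 (2.22), Car4 (2.074), Inhba (1.691), Capn3 (1.311), Fst (1.213), Smim3 (1), Kcnip4 (−1.032), Spata13 (−1.097) and Pcdh19 (−1.506). Tbr1, Car4, Capn3, Fst and Smim3 lay under the NAcc intensity filter, so a fall there might not show, although a rise could.

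In DG 1291 (early) and 1733 (lifetime) features differed from control, and both groups had a wider array range than control. Other splits of the arrays gave at most 1208 and 981 features, and 1 of 100 splits, the real one, gave as many in each. This is the lowest share that 100 splits can give. It argues against chance as the whole cause of the lifetime count without excluding it. The early count lay close to 1208, which points to a structure among the arrays. The slope on array range within groups predicted part of the change of each called feature, with a median share of 37.67% (early) and 39.3% (lifetime). Range and overexpression cannot be told apart for these calls as a whole, because range itself differed between the groups. A further quantile normalization, which gives all DG arrays the same range, left 2 (early) and 3 (lifetime) gene lists past the threshold. Without it the counts were the same. These list counts do not settle the calls of single features. Of the calls, 1 (early) and 71 (lifetime) also passed with the range as a covariate, which argues against range as the whole cause of those 71. With the range as a covariate the median change of the called features went from 0.37 to 0.24 (SE 0.098 to 0.110) in the early and from 0.39 to 0.24 (SE 0.102 to 0.123) in the lifetime group, so the calls ended by a smaller change and a wider error. A lower share of glial and vascular cells predicted a median share of 7.767% and 9.726%, which argues against it as the whole cause. Even so, with it as a covariate only 377 and 699 features passed, 369 and 672 of them among the calls. The median change of the called features went from 0.37 to 0.34 and from 0.39 to 0.35. Unequal amplification and an effect of the receptor stay open.

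Between lifetime and early DG, 155 features differed, with Prss23, Blnk and Car4 at the top, and no other of 100 splits gave over 1 (1 of 100, the real one, gave as many). As a median share over the called features, array range predicted −0.2827% and the glial and vascular mean −0.4728% of the change, which argues against range and glia. Pyramidal and mossy markers differed by a median of 0.1844 (quartiles 0.075 to 0.394) where the risers had 0.57. The risers were selected for passing and the markers were not, so this cannot decide on neighbouring tissue, which stays open. For the 124 of these features that the NAcc filter kept, the NAcc of the same groups showed 5.736% of the DG change (quartiles −13.12% to 18.56%), which argues against a variant carried by the animals; for the other 31 a variant stays open. A gene that acts in DG alone, litter and a hybridization day between the groups stay open, since the labels give neither litter nor day; a biological effect of the duration of overexpression may be proposed only as a hypothesis.

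NAcc early array 5 stood apart with a median of 6.503 (others 6.157 to 6.219), an interquartile range of 1.717 (others 2.281 to 2.422) and a mean correlation of 0.5977 (others 0.9614 to 0.9659). Its slope on the mean of the other NAcc arrays was 0.5052, where the lowest other slope was 0.96. A low correlation lowers this slope as well. The slope therefore cannot tell compressed values of a weak hybridization or amplification from another unlike profile. The DG array of the same animal correlated with the other DG arrays at 0.9759 (median of the others 0.972), which argues against an animal unlike the rest. Its correlation with the DG profile was lower than with the NAcc profile (−0.1018), which argues against DG tissue in its place. A weak hybridization or amplification and a degraded sample stay open.

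Car4 was 7.559 in DG lifetime array 10, against 8.327 to 8.787 in the other lifetime arrays, and above all control arrays of DG. In NAcc early array 5 Car4 was 5.796 (others 5.143 to 5.313) and Ptgr1 5.372 (others 4.943 to 5.098). NAcc lifetime array 8 had a median of 6.272, the others 6.135 to 6.18.

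No feature passed in NAcc early (0, limma, 556 at an unadjusted p under 0.05) or lifetime (0, and 415) against control. All 100 of 100 splits gave as many, as any split must for a count of 0, so this share cannot address chance. The highest other was 0. The 1 feature of NAcc lifetime against early was reached by 1 of 100 splits, the real one (highest other 0). Without early array 5 and lifetime array 8, 3 of 100 splits reached the 9 early features (highest other 52, several times the real count, which points to a structure among the arrays), 1 reached the 279 lifetime features (highest other 120) and 1 the 15 of lifetime against early (highest other 4). For the difference of change between regions, 100 of 100 splits reached the 0 of the early change, as any split must (highest other 14, limma 2206 at an unadjusted p under 0.05). For the lifetime change 2 of 100 reached the 62 (highest other 213, several times the real count, which points to a structure among the animals). Between regions 1 of 100 splits reached 10113 (highest other 6219).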

How the results depend on the processing

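Alternative settings fixed in advance come first in this part. The covariates and the sets of arrays without NAcc early 5 or with lifetime 8 also left out were chosen only after the result was seen, and the cause was not tested for any value that changed. The planned covariate from control probes could not be run, because the values used here hold no control probes. With no filter the counts were 1997 (DG early), 2617 (DG lifetime), 1 (NAcc lifetime), 0 (NAcc lifetime against early) and 16084 (DG against NAcc). Array weights gave 2419, 2937 and 433 in DG (early, lifetime, lifetime against early) and 287, 144 and 61 in NAcc. An adjusted p of 0.10 gave 2479, 2902 and 240 in DG and 2 for NAcc lifetime against early. That last comparison gave 2 with a 60th percentile filter, 0 after quantile normalization, 2 with centred arrays, 0 with trended and robust variances, 0 with only the 2 groups compared and 2 with 1 value per gene, and NAcc lifetime gave 2 with only the 2 groups compared. The replicate block, with paired arrays of both regions, gave 511 and 948 in DG, and 5 (NAcc early) and 1 (NAcc lifetime); no replicate block gave 107 for the lifetime difference between regions. Among the counts of the other comparisons the block moved none by over 1.5 times. In the block fits the correlation between arrays of the same animal was 0.060 (DG features) and 0.055 (NAcc features). The moved counts can therefore come from the variance pooled over both regions. With array range as a covariate the counts were 1 and 74 in DG early and lifetime, and 11, 4 and 0 in NAcc (early, lifetime, lifetime against early). The first residual component gave 261, 426 and 244 in DG, the second 375 in DG early, and the glial and vascular mean 377 and 699 in DG early and lifetime. Without NAcc early 5 the first component gave 10, 10 and 4 in NAcc, the second 5 (lifetime) and 2 (lifetime against early), and array range 2 and 5. Without NAcc early 5 and lifetime 8 together the NAcc counts were 9, 279 and 15, and the differences between regions 36 (early) and 207 (lifetime); the lifetime difference was 31 after quantile normalization of all arrays. Leaving out 1 array gave 213 (early 4) to 2273 (early 1) in DG early and 808 (lifetime 9) to 2611 (lifetime 10) in DG lifetime. Leaving out 1 animal gave up to 30 (without 5) for the early and 29 (without 11) to 397 (without 5) for the lifetime difference between regions. Nr3c1 changed by −0.02 with array range as a covariate in DG early. In NAcc early it changed by −0.005 after quantile normalization, −0.004 with centred arrays, −0.024 without early 4 and 0.165 without early 5. In NAcc lifetime it was 0.42 with array weights and 0.417 without early 5 and lifetime 8. Gene lists past the threshold were 0 in all within-region comparisons with an estimated correlation and all arrays, and 1 (stress axis genes, adjusted p = 0.0469) in NAcc lifetime without early 5, which became 0 (0.0501) without lifetime 8 as well. With array range as a covariate they were 0 (DG early), 6 (DG lifetime against early) and 5 (NAcc lifetime against early), and with array weights 5 (DG lifetime), 5 (DG lifetime against early) and 2 (NAcc early). Quantile normalization gave 5 (NAcc early) and 3 (NAcc lifetime against early), leaving out early 5 gave 4 and 5, and leaving out early 5 and lifetime 8 gave 4 and 4. With an estimated correlation the counts with array range, or without these arrays, were 0 but for the stress axis list. With controls split 3 and 3 the early and lifetime changes correlated at 0.565 in DG and −0.05213 in NAcc, and the early changes of DG and NAcc at 0.1902 without animals 5 and 8. Nfkb2 in DG lifetime (−0.21, not past the threshold) was 0.052 with array range as a covariate. Between regions, quantile normalization of all arrays gave Kdr −0.002, Esam −0.095, Fcrls −0.146, Enpp2 −0.264, Slc2a1 −0.283, Ugt8a −0.3, Cnp −0.322, Grik3 −0.386, Ogn −0.287 and Gpr17 −0.514. Centring gave Esam −0.056, Fcrls −0.072, Enpp2 −0.209, Slc2a1 −0.211, Ugt8a −0.246, Cnp −0.262, Grik3 −0.337, Ogn −0.348 and Gpr17 −0.454. Leaving out 1 animal ended the region calls of Gpr17 (adjusted p = 0.0804 without 9) and Ogn (0.102 without 1).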

Other observations

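The tests of gene families in this part were chosen only after the result was seen; the lists were planned. Splicing factor genes (the Srsf, Hnrnp, Sf3, Snrp and Prpf families) were higher in DG of both overexpressing groups: 10 of 55 rose and none fell in the early group (45 positive, median +0.25, adjusted p over 24 tests 4.50e-05; 0.777 with an estimated correlation), and 8 rose and 1 fell in the lifetime group (median +0.26, adjusted p = 0.000243; 0.777). Proteasome subunit genes had 5 rises of 32 in the early (adjusted p = 0.0106) and 7 in the lifetime group (adjusted p = 0.00166; both 0.777 with an estimated correlation), and none fell. With array range as a covariate neither family passed or had a rise: splicing factors had medians of 0.02849 and 0.037 (adjusted p = 0.217 and 0.543) and proteasome subunits 0.003 and 0.012 (both adjusted p above 0.6), so both rises may come from the arrays. In NAcc splicing factors were lower in the early group (18 of 52 above control, median −0.14, adjusted p = 0.0393; 0.674 with an estimated correlation; median +0.06 and adjusted p = 0.144 without NAcc early array 5 and lifetime array 8) and did not pass in the lifetime group (median +0.09, adjusted p = 0.161; 0.00102 without the 2 arrays, 0.389 with an estimated correlation). Proteasome subunits there had medians of −0.19 and +0.07 (adjusted p = 0.0503 and 0.134; without the 2 arrays 0.444 and 0.0455, the latter 0.652 with an estimated correlation). Both families were higher in lifetime than in early NAcc (adjusted p = 0.00254 each; 0.674 with an estimated correlation), where array 5 is on the early side. Without the 2 arrays the splicing median went from +0.16 to +0.06 (adjusted p = 0.0133, or 0.519 with an estimated correlation). The proteasome median went from +0.33 to +0.07 (0.0763, not past the threshold).

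Protocadherin genes were higher in NAcc after lifetime overexpression, 17 of 17 above control (median +0.16, none passed, adjusted p over 24 tests 1.27e-05; 0.220 with an estimated correlation), with Pcdh19 the largest. Without NAcc early array 5 and lifetime array 8, 3 passed (adjusted p = 1.41e-06), but 0.2163 with an estimated correlation leaves open whether the family moved beyond the correlation between its members. In the early group the family did not pass (12 of 17 above control, median +0.11, none passed, adjusted p = 0.0660); without the same 2 arrays 15 of 17 were above control (1 passed, adjusted p = 1.47e-05; 0.216 with an estimated correlation). In early DG 3 of 19 rose (adjusted p = 0.00699; 0.777), and none with array range as a covariate (adjusted p = 0.217); in lifetime DG 3 rose and 1 fell (median +0.06, adjusted p = 0.177). Zinc finger genes were higher in NAcc in 135 of 203 after early (median +0.06, adjusted p = 0.00745; 0.304 with an estimated correlation) and in 134 of 203 after lifetime overexpression (median +0.05, adjusted p = 0.0191; 0.343).

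The other lists of DG, in the order early and lifetime, were as follows. Chromatin genes had 4 rises and 2 falls of 27 in each (adjusted p = 0.274 and 0.176), heat shock genes 2 and 1, then 3 and 1 of 24 (0.682 and 0.737; early median −0.01, mean +0.06, test upward), Wnt signalling genes 2 and 1, then 3 and 0 of 18 (0.944 and 0.838), MAPK and neurotrophin genes 2, then 3 rises of 28 (0.0803 and 0.0804) and GABA genes 2 and 0, then 3 and 1 of 18 (0.195 and 0.529). Presynaptic genes had 1 rise and 1 fall, then 2 and 2 of 27 (0.864 and 0.850; median +0.02, mean −0.02, test upward in both), serotonin and noradrenaline receptors 1 and 1, then 0 of 7 (0.682 and 0.268; early mean +0.005 against a downward test), circadian genes 0, then 2 and 1 of 16 (0.682 and 0.806) and neuropeptides 1 fall, then 0 of 14 (0.0520 and 0.537; the feature of Sstr2 not counted in the list passed in lifetime DG, +0.47, adjusted p = 0.0382, and the counted one had the opposite sign, −0.05). Markers of all medium spiny neurons had 1 rise and 1 fall, then 1 and 2 of 13 (0.682 and 0.583), myelin lipid genes 1 and 1, then 0 and 1 of 18 (0.961 and 0.911; early mean +0.002 against a downward test), meningeal markers 0 of 9 (0.882 and 0.799) and inflammation genes 0 of 12 (0.450 and 0.196).

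Axon guidance genes had 7 rises and 3 falls of 35 in lifetime DG (median −0.04, mean +0.07, test upward, adjusted p = 0.911) and sodium and calcium channel genes 5 and 4 of 26 (median −0.04, mean +0.02, test downward, adjusted p = 0.947).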
